A study of Mus musculus with 2 samples.

How the data were processed

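The series measured miRNAs by sequencing RNA fragments shorter than 30 nucleotides from the left cerebral cortex of 2 male B6CASTF1/J mice. The labels give each library its own biological replicate number and animal number. Both samples also carry the same donor identifier, so their separate origin rests on those numbers. They formed 1 group, so no comparison between groups was made, and with n = 2 each SD rests on 2 values.

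The authors deposited 1 table per library with whole-number read counts per miRNA gene, which are not normalized. Per the labels and the deposited descriptions, the genome build was mm10 and the annotation GENCODE M21. Each table holds 3 count columns and 4 tally rows for reads that were unmapped, mapped to several places, outside the genes or ambiguous. This is the layout of STAR's gene counts, in which a read that maps to more than 1 place is tallied apart and given to no gene. The aligner, its version and the trimming of adapters are not given in the sources used here, so the handling of such reads is read from the layout of the deposited counts. It matters for miRNAs, because copies of a miRNA at different loci share the mature sequence and their reads cannot be placed. The reads come from hybrid mice, and mm10 is the sequence of the C57BL/6J parent, so a read that differs from it may have been lost.

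The tally rows were kept out of library sizes and tests. Their shares were 19.6% and 18.9% unmapped, 41.7% and 41.1% mapped to several places, and 5.03% and 4.94% unique but outside the sense strand of miRNA genes, in libraries 1 and 2. The ambiguous tally held 0 reads and 1 read. The sense-strand column was taken as the stranded column with the larger total in both libraries. CPM values are counts per 1000000 sense-strand reads in miRNA genes, and log2 values used a pseudocount of 1 CPM. Ratios of CPM between the libraries used no pseudocount, and fold ranges within clusters used 1 CPM. A gene was called detected with 10 or more reads in both libraries. All 2202 gene identifiers matched GENCODE M21, which gave the symbols, coordinates, host genes and hairpin sequences. For 12 genes the symbol differs from the miRNA's usual name and was matched by hand.

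Each gene with 10 or more reads in total was tested between the libraries with a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment at 0.05. Intervals of ratios are exact 95% intervals, and shares of reads carry Wilson or exact 95% intervals. A gene at 0 was given the limit of 3 counts of the total. The spread between the samples was estimated with edgeR 4.0.16 (TMM factors, intercept-only design, common dispersion) in R 4.3.3. DESeq2 1.42.0 and edgeR's exact test at the common dispersion were alternatives. Other steps used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6.

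The tests of the main results, the rule for named genes, 18 gene lists, 19 clusters, 29 multi-copy families and the alternatives were fixed before the data were examined. Several explanations weighed for flagged results and the alternative without the mir-144~mir-451a pair came later and are marked as such below. The genes named are the 20 with the highest mean CPM, the 1 to 3 highest members of each list, and the 5 genes higher in each library with the largest ratio among those with a mean of at least 100 CPM that passed the binomial test. The rule adds the 3 genes with the most antisense reads, and the highest and lowest members of the 3 clusters with the widest range. Members of lists, multi-copy families or clusters outside this rule are named as examples, chosen after their values were seen. The lists cover neurons, oligodendrocytes, the miR-29 family of astrocytes, microglia and leukocytes, red blood cells, vessels, choroid plexus and ciliated cells, liver, muscle, pancreas, gut, epithelium and skin, sensory organs, pluripotent cells, the let-7 family and the Dlk1-Dio3, Sfmbt2 and X-linked testis clusters. A list's median log2 CPM was set against 10000 random lists of the same size from all annotated miRNA genes.

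The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. The binomial test called 63.8% of 69 genes changed 1.5-fold, 68.2% of 66 genes changed 2-fold and 95.2% of 62 genes changed 4-fold, all in the right direction, and 3 of 301 unchanged genes. The counts for the binomial test held counting error only, without a spread between samples. These call rates therefore do not carry over to libraries that differ beyond counting error. Simulated coefficients of variation of 0.1, 0.3 and 0.5 were recovered over 406 genes as 0.1085, 0.2864 and 0.4895. The alternatives were the column that ignores strand, other count minimums, other scalings and pseudocounts, other denominators and leaving out each library in turn. Mature arms, isomiRs and parental alleles were not analysed here.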

Results

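MicroRNAs (miRNAs) were sequenced from the left cerebral cortex of male mice aged 2 months. The animals were B6CASTF1/J, first-generation hybrids of the C57BL/6J and CAST/EiJ inbred strains. The series held 1 group of 2 animals with 1 library each, numbered male 3 (library 1) and male 4 (library 2) in the labels. Both samples carry the same donor identifier in the labels, so that they come from separate animals rests on the animal and replicate numbers, and the spread between them may be partly or wholly technical. With 1 group, the series contained no comparison between conditions, and each value below is given with the spread between the 2 libraries. Library 1 held 11372894 reads and library 2 held 12980686 reads. Of these, 3827158 reads (33.7%, 95% Wilson interval 33.62 to 33.68%) and 4553291 reads (35.1%, 35.05 to 35.10%) were counted on the sense strand of an annotated miRNA gene. Reads without molecular identifiers are not independent molecules, so all intervals and limits cover counting error only. Counts were given per precursor gene, and the arms of a hairpin were not separated.

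Among reads placed at a single gene, Mir139 had the highest mean, at 115590 ± 30882 counts per 1000000 sense-strand miRNA reads (CPM; SD, n = 2), or 11.6% of these reads. It led in library 1, whereas in library 2 Mirlet7g was higher (115681 CPM against 93753 CPM for Mir139). Mirlet7g followed in the mean at 103234 ± 17603 CPM, with Mirlet7b at 74883 ± 1262 CPM and Mirlet7i at 55159 ± 9976 CPM, all members of the let-7 family that is abundant in differentiated tissue. Mirlet7d (44847 ± 8439 CPM), Mir127 (43068 ± 10492 CPM), Mir744 (41966 ± 2336 CPM), Mir132 (39333 ± 12985 CPM), Mirlet7e (35299 ± 960 CPM) and Mir23b (20652 ± 1176 CPM) completed the top 10. These 10 genes held 57.4% ± 0.393 of the sense-strand miRNA reads (SD, n = 2), with 57.1% in library 1 and 57.7% in library 2. The next 10 genes ranged from Mir652 at 14457 ± 3432 CPM to Mir128-1 at 10137 ± 5296 CPM, and included Mir125a, Mir328, Mir433, Mir151, Mir770, Mir330, Mir29a and Mir99a. Of 2202 annotated miRNA genes, 406 had 10 or more reads in both libraries and are called detected here, 199 had a mean of at least 100 CPM, and 1444 had no read in either library. For a gene without a read, a count of 0 allowed up to 7.84e-05% of the sense-strand reads in library 1 and 6.59e-05% in library 2.

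Most of the leading genes lie inside longer genes (mm10 coordinates, GENCODE M21 annotation). Mir139 (ENSMUSG00000065446.1; chromosome 7, 101475376 to 101475443, plus strand) lies in an intron of Pde2a, which encodes a phosphodiesterase. Mirlet7g (ENSMUSG00000065440.1; chromosome 9, 106178840 to 106178927, plus strand) lies in an intron of Wdr82. Mirlet7b (ENSMUSG00000065564.1; chromosome 15, 85707319 to 85707403, plus strand) lies in an exon of the non-coding transcript Lncppara. Mir744 (ENSMUSG00000076460.1; chromosome 11, 65734733 to 65734832, minus strand) lies in an intron of Map2k4. Mir132 (ENSMUSG00000065537.2; chromosome 11, 75173682 to 75173747, plus strand) lies in an intron of the processed transcript 1700016P03Rik. Mirlet7i (ENSMUSG00000065406.3; chromosome 10, 122985640 to 122985724, minus strand) has no annotated host gene on its strand.

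The let-7 family as a whole, 12 genes fixed as a list, held 32.3% ± 3.49 of the sense-strand miRNA reads (SD, n = 2). Its share was 29.9% in library 1 and 34.8% in library 2. By the exact binomial test 9 members were higher in library 2 against 2 in library 1, with the same counts when adjusted over the list alone. That test allows for counting error only, and 246 of all 508 genes tested (48.4%) differed by it. The counts for the lists below stand against that share, which covers genes of all depths. With many reads the test calls even small differences, and Mirlet7b passed it at 1.02-fold. A list of abundant genes may therefore exceed that share through depth alone. Within the family the reads were uneven. The 6 loci whose hairpins share no stretch of 20 bases with another annotated hairpin ranged from Mir98 at 3922 CPM to Mirlet7g at 103234 CPM. The other 6, the paired copies of let-7a, let-7c and let-7f, ranged from Mirlet7a-2 at 192 ± 88.0 CPM to Mirlet7f-2 at 3186 ± 109 CPM, and all lay below Mir98. Copies of other miRNAs ranged widely. Mir128-1 (10137 CPM), Mir138-1 (5240 CPM) and Mir219a-2 (2057 CPM) were abundant. The 3 Mir124a genes, which encode a miRNA well known as a marker of neurons, reached only 3.28, 0.899 and 0.894 CPM, and Mir9-1, Mir9-2 and Mir9-3 reached 12.2, 1.79 and 56.7 CPM. Across 29 multi-copy families with 60 loci, the counts summed to 3.55% ± 0.424 of the miRNA reads (SD, n = 2), 45 loci were detected and 10 had no read. Reads mapped to several places, which the layout of the count files gives to no gene, made up 41.7% of library 1 and 41.1% of library 2, so the counts of multi-copy genes are uncertain, and low values there cannot be read as low expression.

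The imprinted Dlk1-Dio3 region on chromosome 12, whose miRNAs are transcribed from the maternal chromosome and are prominent in brain, held 12.4% ± 1.24 of the sense-strand miRNA reads (SD, n = 2). Of its 51 listed genes, 48 were detected. Mir127 (ENSMUSG00000070076.2; 109592846 to 109592915, plus strand), which lies opposite an exon of Rtl1, was the highest, followed by Mir433 at 12700 ± 1267 CPM, also opposite Rtl1, and Mir770 at 11424 ± 2221 CPM in an exon of Meg3. By the exact binomial test 21 members were higher in library 1 and 16 in library 2, both over all genes tested and adjusted over the list alone. The median log2 CPM of the list was 8.90. It lay at percentile 100 of 10000 random lists of the same size, but with 1444 genes at 0 this sets few lists apart, and the epithelium and skin list lay at percentile 99.4.

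Neuron-enriched miRNAs held 6.74% ± 1.77 of the sense-strand reads (SD, n = 2), and 15 of the 18 listed genes were detected. Mir132, which is induced by neuronal activity, supplied most of these reads, followed by Mir128-1 at 10137 ± 5296 CPM and Mir137 at 5347 ± 241 CPM. The share was 7.99% in library 1 (95% interval 7.97 to 8.02%) and 5.49% in library 2 (5.47 to 5.51%). Mir132 was 1.61-fold and Mir128-1 2.17-fold higher in library 1, while Mir137 differed by 1.07-fold. In all, 6 members were higher in library 1 and 4 in library 2 by the binomial test, with the same counts adjusted over the list alone. Neither Mir132 nor Mir128-1 passed edgeR's exact test, which also allows for the spread between the samples.

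Glial and vascular miRNAs were present at lower shares. The miR-29 family, which is strong in astrocytes, held 1.21% ± 0.317 of the sense-strand reads (SD, n = 2), mostly from Mir29a at 10625 ± 2718 CPM, with Mir29c at 1314 ± 414 CPM. Its 4 members were detected, 3 were higher in library 1 and none in library 2. The oligodendrocyte list held 0.422% ± 0.107, from Mir338 at 2161 ± 815 CPM and Mir219a-2 at 2057 ± 256 CPM, with 2 of 3 detected members higher in library 1. The vascular list held 1.65% ± 0.298, led by the endothelial Mir126a at 9962 ± 2634 CPM and the smooth muscle Mir143 at 6265 ± 373 CPM, with 2 members higher in library 2 and 1 in library 1. The microglia and leukocyte list held 0.196% ± 0.0292, led by Mir150 at 1155 ± 191 CPM and Mir146 at 708 ± 96.0 CPM, while Mir142 stood at 44.3 ± 1.21 CPM. Mir146, Mir150 and Mir223 (61 and 8 reads, below the detection minimum in library 2) were higher in library 1, and no member was higher in library 2. The choroid plexus and ciliated cell list held 0.0732% ± 0.000599, from Mir204 at 444 ± 19.7 CPM and Mir34c at 243 ± 13.1 CPM, and none of its 5 detected members differed between the libraries. These counts were the same when adjusted over the list alone. With edgeR's exact test, which also allows for the spread between the samples, only Mir223 of the genes in these lists differed.

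The lists for other organs held small shares of the counted reads. The liver miRNA Mir122 was at 75.5 ± 4.42 CPM (SD, n = 2) and the pancreatic islet miRNA Mir375 at 153 ± 29.5 CPM. The pancreas list held 0.0156% ± 0.00290 of the sense-strand reads, the epithelium and skin list 0.0182% ± 0.00541 with Mir203 at 78.2 ± 32.0 CPM, the sensory organ list 0.00349% ± 0.00109 with Mir183 at 22.5 ± 8.15 CPM, the muscle list 0.00330% ± 0.000861 with Mir206 at 29.5 ± 5.84 CPM, and the gut list 0.00285% ± 0.000991 with Mir194-2 at 19.5 ± 10.8 CPM. By the exact binomial test 2 epithelium and skin genes, 1 sensory organ gene and 1 gut gene were higher in library 1, and 1 pancreas and 1 muscle gene in library 2. Adjusted over the list alone these counts were the same except for muscle, where 2 genes were higher in library 2, and Mir122 did not differ. Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2, Mir133b and Mir194-1 had no reads, but each shares a stretch of at least 20 bases with another hairpin, so the muscle and gut shares carry the limit given for multi-copy genes. Mir215 of the gut list also had no reads but shares no such stretch, so that limit does not cover it. The pluripotent cell list had 10 reads in library 1 and 4 in library 2 over 11 genes. The X-linked testis list had 1 and 4 reads over 18 genes, of which 16 had none. The Sfmbt2 list of repeat-derived miRNA genes held 0.152% ± 0.00418, led by Mir467d at 699 ± 129 CPM, with 69 of 81 genes at 0, 4 genes higher in library 1 and 1 higher in library 2, also when adjusted over the list alone.

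**Figure D1:**
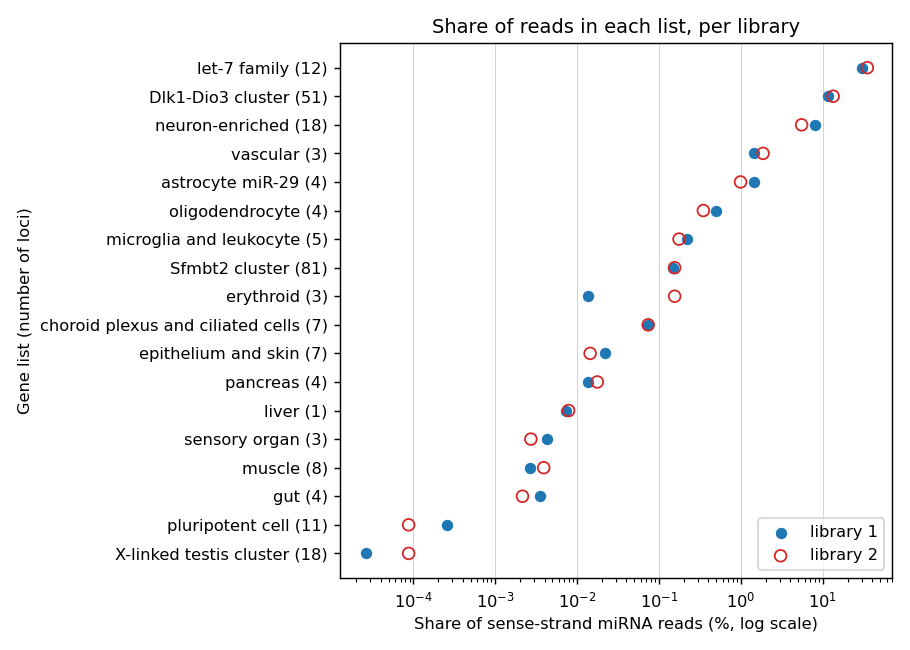
Share of sense-strand miRNA reads (percent, log axis) in each of 18 gene lists, with the number of loci in parentheses; filled points are library 1 and open points library 2. The let-7 family lies highest at 29.9 and 34.8%, and the erythroid list shows the widest gap among lists with detected members, at 0.0134 and 0.155%.

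The 2 libraries ranked miRNA genes alike but differed beyond counting error at many of them. Mir451a, a miRNA of red blood cells, had 223 reads in library 1 and 6459 in library 2, a 24.3-fold difference in CPM (log2 ratio of library 1 over library 2 -4.61, 95% exact interval -4.80 to -4.41). Mir26a-2 went the other way, with 1722 reads in library 1 and 42 in library 2 (48.8-fold, log2 ratio 5.61, 5.17 to 6.09). Mir185 was 8.63-fold higher in library 2 (755 and 7751 reads, log2 ratio -3.11). Mir21a was 4.43-fold, Mir487b 3.38-fold, Mir140 3.31-fold and Mir22 3.15-fold higher in library 1. Mir99b was 3.12-fold, Mir153 2.20-fold and Mirlet7a-2 1.96-fold higher in library 2. The erythroid list as a whole held 0.0134% of library 1 and 0.155% of library 2. Its other members were Mir144, 3.91-fold higher in library 2 (94 and 437 reads), and Mir486, 1.47-fold higher in library 1 (195 and 158 reads), and each differed by the binomial test, also when adjusted over the list alone.

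Over the 406 detected genes, log2 CPM correlated across genes with Pearson's r = 0.982 and Spearman's rho = 0.978, where genes are not independent replicates. The median absolute difference was 1.28-fold, 295 genes (72.7%) lay within 1.5-fold, and 41 differed by 2-fold or more, 28 of them higher in library 1 and 13 in library 2. By the two-sided exact binomial test with Benjamini-Hochberg adjustment, 246 of 508 genes tested (48.4%) differed, 128 higher in library 1 and 118 in library 2. The libraries were therefore not 1 library deposited under different names. This test compares the 2 libraries with counting error alone and says nothing of any condition. The coefficient of variation between the 2 samples beyond counting error, from edgeR's common dispersion, was 31.5%. For edgeR's exact test the common dispersion was fitted anew over the 508 genes tested. When that spread was allowed for, 4 of 508 genes still differed (25 at an unadjusted p under 0.05). These were Mir26a-2 (adjusted p = 2.61e-08), Mir451a (adjusted p = 2.71e-06), Mir185 (adjusted p = 0.00585) and Mir223 (adjusted p = 0.0459; 61 and 8 reads), the last named only after its values were seen. The dispersion in this test came from the same 2 libraries, so its p-values describe how far these genes stand from the rest and are no replicated test.

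**Figure D2:**
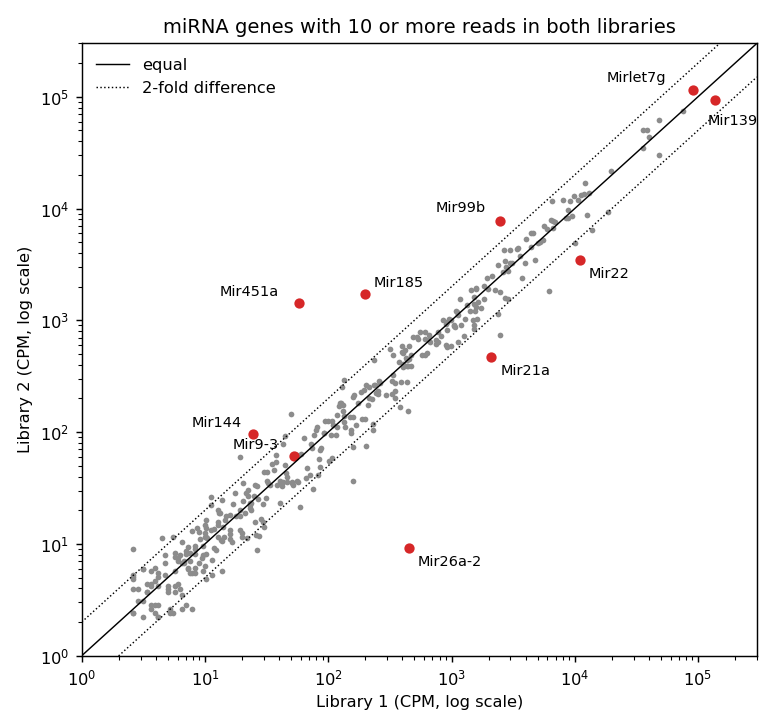
CPM of each of the 406 detected miRNA genes in library 1 (x axis, log scale) against library 2 (y axis, log scale), 1 point per gene; the solid line marks equal values and the dotted lines a 2-fold difference. Mir451a (24.3-fold) and Mir185 (8.63-fold) lie far above the diagonal, and Mir26a-2 (48.8-fold) far below it.

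MiRNA genes that sit together in clusters, and whose precursors can be cut from a shared transcript, differed widely in count. In the mir-379~mir-410 cluster Mir382 reached 9287 ± 671 CPM and Mir494 13.5 ± 3.51 CPM (SD, n = 2), a 642-fold range with 1 CPM added to both, as in the other ranges here. In mir-23b~mir-24-1, Mir23b was 382-fold above Mir24-1 (53.0 ± 31.5 CPM), but 260-fold in library 1 and 677-fold in library 2. In mir-29b-1~mir-29a, Mir29a was 168-fold above Mir29b-1 (62.4 ± 29.2 CPM). Mir24-1 and Mir29b-1 have a second copy with the same mature sequence, so their counts carry the limit given above for multi-copy genes. The median range over 19 clusters was 22.6-fold. The ratio between the libraries also varied within a cluster. Mir99b, Mirlet7e and Mir125a lie together on chromosome 17 (17830188 to 17830879), and their log2 ratios were -1.64, 0.06 and 0.99.

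**Figure D3:**
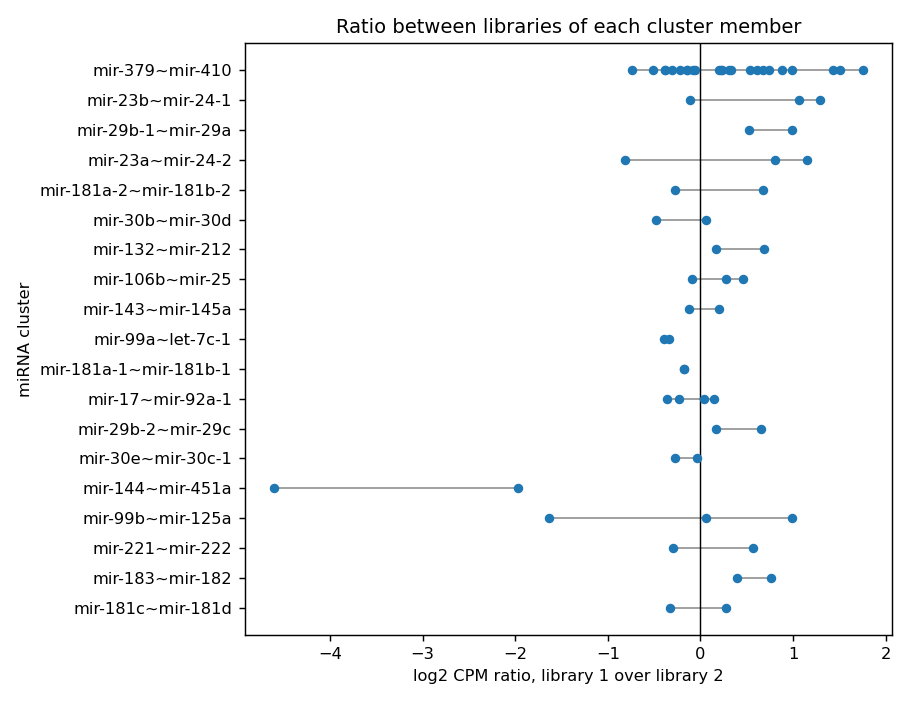
Log2 ratio of CPM, library 1 over library 2, for every detected member (point) of 19 miRNA clusters (rows); the grey line joins the lowest and highest member and the vertical line marks equal values. Both members of mir-144~mir-451a lie below 0, at -1.97 and -4.61, and the members of mir-99b~mir-125a spread from -1.64 to 0.99.

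Reads fell on the annotated strand of miRNA genes. The sense column held 93.2% of the summed entries of both stranded columns in library 1 and 93.1% in library 2. A read at a pair of overlapping miRNA genes on opposite strands enters both columns, so these are not shares of reads. With each read counted once, the sense strand held 99.9954% of reads in library 1 (95% exact interval 99.9947 to 99.9961%) and 99.9968% in library 2 (99.9963 to 99.9973%). All but 175 antisense entries in library 1 and 145 in library 2 lay at genes annotated opposite another miRNA gene. Gm25927 had 137692 and 157632 antisense entries, the counts of Mirlet7e on the other strand, Mir126b had 30996 and 53839, opposite Mir126a, and Gm24083 had 36207 and 38668, opposite Mir191. Without genes whose antisense reads exceeded their sense reads, the mean sense share was 99.9964%. That filter raises the share by construction, so this value is no separate evidence. In the column that ignores strand, all 30 genes with 10 or more sense reads and an overlapping miRNA gene on the other strand lost at least 90% of their reads, and Mirlet7e fell from 137692 and 157632 reads to 0, and Mir451a from 223 and 6459 to 0.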

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

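The explanations by scaling, shared transcripts, counting error, shared copies and neuronal RNA in this part were set only after the result was seen. So were their bounds and the doubt over Mir486 in the red blood cell test. The exact binomial test used for counting error was itself fixed beforehand. The design has 1 group, so no biological difference between groups was tested.

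Several tallies and columns outside the main counts held more than a count of 0 allows. Reads mapped to several places made up 41.7% of library 1 and 41.1% of library 2. Uniquely mapped reads outside miRNA genes made up 5.03% and 4.94%. The antisense column held 277760 entries in library 1 and 335195 in library 2 at genes opposite an overlapping miRNA gene, which are reads already counted on the sense strand of that gene. Only 175 and 145 antisense reads lay elsewhere.

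Low counts of multi-copy genes were the first pattern weighed. In the let-7 family the 6 loci without a shared stretch of 20 bases had a median of 50003 CPM and the 6 with one a median of 448 CPM, a contrast that prompted the question and so was not tested. For reads left out because they map to several copies, the comparison within the neuron-enriched list, which holds the Mir124a and Mir9 copies, gave 3029 CPM at 4 loci against 90.7 CPM at 14, a ratio of 33.4 (two-sided exact permutation p = 0.140), which leaves that explanation open, because only 4 loci share no stretch and the list holds the genes that prompted it. The unshared neuronal loci had a median at percentile 86.7 of the detected genes, so these 4 loci were not low as a set. A partial loss of neuronal RNA could not be judged from that rank, because no reference sample gives the level without loss.

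The higher Mir451a in library 2 was the second. Depth or scaling is argued against, since it would move all genes by 1 factor and leave no gene apart. The log2 ratio of unscaled counts was -4.86 for Mir451a and -0.25 in the median of the 406 detected genes. This gap of -4.61, which no common factor can change, restates the CPM ratio and is no separate test. By the bound set beforehand, more white blood cell RNA is argued against too, with a median log2 ratio of 0.17 over the 4 detected microglia and leukocyte genes. Mir223, left out of that median, was higher in library 1. The list also covers microglia, so its median could miss a change in white blood cells alone. More red blood cell RNA was not settled by these counts. The mark set beforehand was that Mir144 and Mir486 each be at least 4-fold higher in library 2, beyond the spread of all genes' ratios. Mir144, from the same cluster as Mir451a, was 3.91-fold higher, a log2 ratio of -1.97 (95% exact interval -2.30 to -1.64, counting error only). It did not pass edgeR's exact test at the common dispersion (adjusted p = 0.430). Mir486 went the other way, at 0.55, which had been set beforehand as evidence against more red blood cell RNA. The Mir486 hairpin shares 22 bases with Mir3107 on the opposite strand, the length of a mature miRNA. Such reads map to both and are not counted in either library, and whether that alters the ratio was not tested. By the bounds set beforehand, the Mir486 ratio falls on the side against more red blood cell RNA. Its counts leave out reads of the shared stretch, so that ratio cannot decide the question. Mir144 was higher in library 2, as more red blood cell RNA predicts. Its 3.91-fold difference fell just short of the 4-fold mark, which lies within its interval.

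The spread of ratios between the libraries was the third. Counting error alone is argued against, as 48.4% of genes tested differed by the exact binomial test. GC content of the hairpin is argued against, with Spearman's rho = 0.00578 over 406 genes (permutation p = 0.905) and 41 genes at 2-fold or more both before and after the trend was removed. Differing transcription of shared precursors predicts that cluster members move together: the SD of log2 ratios within 19 clusters was 0.69 against a median of 0.89 in 10000 reassignments (one-sided permutation p = 0.00820), but this rested on the mir-144~mir-451a pair. Without that pair it was 0.64 against 0.62 (p = 0.784 in the same permutation test), no lower than chance, and Mir99b and Mir125a of 1 cluster stood at -1.64 (95% exact interval -1.67 to -1.61) and 0.99 (0.97 to 1.01), which argues against shared transcription as the whole cause in the other 18 clusters.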

How the results depend on the processing

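With 2 libraries, leaving out either one gives the other's value, so those alternatives say nothing about stability. The alternative without the mir-144~mir-451a pair was chosen after seeing the data: the within-cluster SD of log2 ratios went from 0.69 to 0.64 and no longer lay below the reassignments. Detected genes rose from 406 to 615 with 1 read as the minimum. They fell to 295 with a minimum of 50 reads, and to 380 in the column that ignores strand. The coefficient of variation was 0.343 without a filter on low counts and 0.290 by DESeq2, against 0.315. Genes differing between the libraries fell from 246 to 4 with edgeR's exact test, which adds the spread between the samples to counting error. Pearson's r became 0.986 over all genes with a read, and Spearman's rho was 0.978. In the column that ignores strand the top 10 genes held 59.7%, since genes opposite another miRNA gene are lost there. That top 10 was chosen anew, with Mir652 in place of Mirlet7e. Over all uniquely mapped reads the shares were 50.1% for the top 10 genes, 10.9% for Dlk1-Dio3, 28.3% for let-7 and 3.10% for multi-copy loci. Without Mir139 they were 53.4% (with the top 10 genes chosen anew), 14.0%, 36.5% and 4.03%. The median range within clusters was 22.2-fold with a pseudocount of 10 CPM, 26.2-fold over all members, 19.8-fold without multi-copy members, and 23.1- to 23.4-fold in single libraries. The sense share of both stranded columns was 99.9964% without genes whose antisense reads exceed their sense reads, a filter that raises this share by construction. Of the 10 named ratios between libraries, 7 did not pass edgeR's exact test. In the column that ignores strand, the CPM of 22 named genes moved by more than their SD. Some of these, such as Mir338, lost their reads, while others kept them. Mirlet7b had 290016 and 336906 reads there against 290005 and 336901 on the sense strand. Its CPM rose from 74883 to 80787 because the column total fell. Mir451a, whose SD exceeds its mean, lost all its reads. Where the text gives no construction, the cause was not tested. Genes with fewer than 10 reads are limited by depth.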

Other observations

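Mir26a-2 and Mir185 differed between the libraries by more than most genes, and neither belongs to a list fixed for a cell type. Mir26a-2 (chromosome 10, 126995530 to 126995613, plus strand, in an exon of Ctdsp2) had 450 CPM in library 1 and 9.22 CPM in library 2. Mir185 (chromosome 16, 18327401 to 18327465, minus strand, in an intron of Tango2) had 197 and 1702 CPM. Mir26a-1, a copy of Mir26a-2, had a mean of 8.15 CPM, and both carry the limit of multi-copy genes. No explanation was tested for either gene.

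In 11 of 19 clusters the log2 ratios of members had both signs. In mir-23a~mir-24-2 the log2 ratios ran from -0.82 to 1.16, and in mir-99b~mir-125a from -1.64 to 0.99. The widest range apart from mir-144~mir-451a was in mir-99b~mir-125a, ahead of mir-379~mir-410 at -0.74 to 1.76. In mir-99a~let-7c-1 they ran from -0.40 to -0.34, and in mir-181a-1~mir-181b-1 both were -0.18.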
